A study of Capsaspora owczarzaki with 33 samples.

How the data were processed

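The series covered 3 life stages of Capsaspora owczarzaki, a unicellular relative of animals: adherent filopodial cells, aggregative cells and cystic cells. It held 33 libraries. Of these, 12 were chromatin immunoprecipitation libraries of histone marks (4 marks in 3 stages, with 1 library per mark and stage), 5 were ATAC libraries and 4 were RNA-seq libraries of filopodial cells, 2 treated with the histone deacetylase inhibitor trichostatin A (TSA) and 2 with its solvent DMSO. The 9 libraries of RNA polymerase immunoprecipitation and the 3 input libraries were not analysed here. Groups were taken from the sample titles, sources and characteristics in the labels.

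Per the submitters' processing notes, Bowtie 1.1.1, SAMtools 1.1 and MACS2 were used for the histone mark and ATAC libraries, and Bowtie, bedtools and kallisto were named for the later libraries, without a version. The genome build, the settings and the transcript set were not given in the sources used here. The authors deposited 1 peak list per histone mark library, 9 in the narrow and 3 in the broad layout of the peak caller. In these lists the deposited score was 10 times the −log10 q cut to a whole number, the deposited fold was the enrichment over the control, and the remaining deposited columns were the −log10 of the p-value and of the q-value. These values belong to single peaks as the authors' caller gave them, and were used only to describe or filter peaks. Narrow lists held several summits on one interval, and identical intervals were counted once. H3K36me3 was deposited as broad regions. Since peaks were called on single libraries, no spread between replicates could be had for any histone mark. Read depth was not given in the files, so intervals on shares cover counting error only, and the depth behind each peak is unknown.

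Nucleosome-free ATAC sites came as 1 list merged by the authors over the 3 stages. Per the names in that file, a site was called in filopodial and aggregative cells at a q of 0.001 and in cystic cells at 0.01. The labels list 2 ATAC libraries each for filopodial and aggregative cells and 1 for cystic cells. The stage of each site was read from those names. The deposited TPM table (relative transcript abundance, computed by the authors with kallisto per the submitters' processing notes) had 8741 rows, 1 per transcript model, of which 18 were merged pairs of models. TPM have a fixed sum in every library and hold no depth. No column of per-sample values was left unused.

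Peak positions were compared with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. The end of the last feature stood for the length of each of 48 sequences, which gave a span of 27458752 bp. Regions of a mark were merged over stages wherever peaks overlapped by at least 1 bp. Shares carry Wilson 95% intervals. Overlap between marks, and between sites and marks, was tested two-sided against 1000 circular shifts within the 19 sequences of at least 100000 bp, which held 99.4% of the span; the smallest p these shifts can give is 0.002. P-values were adjusted by Benjamini-Hochberg within each family. These tests ask about placement on the genome in these libraries, not about a difference between conditions. Whether stage-specific sites carried stage-specific marks was tested with 1000 rotations of the site labels along the genome, with a mark counted within 500 bp of a site. That test, and the rule for single sites (the highest fold of an H3K27ac peak called in the stage of a site accessible in that stage alone), were chosen after the stage names in the site list had been seen. On simulated data the shift test detected planted overlap of 2%, 5% and 10% in 20 of 20 runs each, and gave 2 detections in 40 runs with none planted.

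TSA was compared with DMSO by limma 3.58.1 in R 4.3.3 with a mean-variance trend on log2(TPM + 1), for 8302 transcripts with a mean of at least 1 TPM over the 4 libraries. A transcript was called changed at a Benjamini-Hochberg adjusted p below 0.05. A fold change on this scale understates the change of low transcripts. Nothing in the labels says that the 2 libraries of a group came from separate cultures, so p-values measure only the spread between these libraries, which may be technical. With 2 libraries against 2, an exact permutation test of a single value cannot go below 0.333. In simulated values for the 8302 transcripts, the fit recovered 0% of 50 transcripts changed 1.25-fold, 34% of 50 changed 1.5-fold, 84% of 50 changed 2-fold and 90% of 50 changed 4-fold, with 4 false calls (3.7% of calls). Only these transcripts were changed, in random directions and without a shift of a whole library. These rates need not hold where most transcripts change.

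Of the table's identifiers, 8722 named a single model, and 8000 of these matched a locus tag of the reference gene table of assembly C_owczarzaki_V2, which lists 8793 genes and gives 0 symbols other than the locus tag. Without product names, the planned gene lists could not be formed, and the rule fixed before the data were examined then allowed 2 identifiers that rose and 2 that fell: those with the largest log2 change among called transcripts with a mean of at least 5 TPM in the higher group and no overlap between the libraries of both groups. Since the files name no genome build, the reference table served only for which genes neighbour each other, and peaks were not assigned to genes. The planned comparisons of expression with marks, of promoter marks between stages and of site positions relative to genes were therefore not run. Neighbour correlations used 1000 permutations of the changes over 7718 genes. In simulated values for these genes, a correlation of 0.05 or of 0.1 planted between neighbours lay above all permutations in 10 of 10 runs, and 0 of 10 runs did so with none planted. Alternatives covered the pseudocount, the filter, rescaling, the replicate block, each library left out, a −log10 q of at least 10, equal numbers of top-ranked peaks, the required overlap and the random placement.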

Results

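Histone marks were mapped in filopodial, aggregative and cystic cells of Capsaspora owczarzaki, together with accessible chromatin in the same stages and the transcriptome of filopodial cells treated with trichostatin A (TSA), an inhibitor of histone deacetylases. H3K4me3 is known as a mark of promoters, H3K27ac of active regulatory DNA, H3K4me1 of regulatory DNA around promoters and at enhancers of animals, and H3K36me3 of transcribed gene bodies. There was 1 library per mark and stage, so values of the marks have no replicate error and differences between stages could not be tested. The RNA-seq part had 2 libraries per group.

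The first comparison asked how much of the genome each mark occupied in each stage. H3K4me3 formed 7575 intervals in filopodial, 7484 in aggregative and 7074 in cystic cells, which covered 20.9%, 20.5% and 18.1% of the span. H3K27ac formed 8385, 8676 and 7766 intervals over 17.9%, 18.5% and 15.6% of it. H3K4me1 had 10085 filopodial and 10187 aggregative intervals but 7871 cystic ones, and its covered share was 18.5%, 19.8% and 14.2%. H3K36me3 covered the most, with 4525, 4391 and 4446 regions over 39.9%, 38.0% and 37.6%. Median widths in filopodial cells were 693 bp for H3K4me3, 543 bp for H3K27ac, 461 bp for H3K4me1 and 1812 bp for H3K36me3. The median cystic H3K4me1 interval was 396 bp wide, against 484 bp in aggregative cells. The authors' median fold enrichment was highest for H3K4me3 (3.55, 3.59 and 3.57) and lowest for H3K36me3 (1.54, 1.58 and 1.54). At a −log10 q of at least 10, H3K36me3 kept 827, 1478 and 613 regions, so most of its regions lay below that limit. They covered 9.63%, 18.38% and 9.04% of the span, less than H3K4me3 at the same limit (20.66%, 20.28% and 17.77%). Cystic H3K4me1 kept 5031 of 7871 intervals.

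The next comparison asked which regions kept a mark across stages. With all deposited peaks, H3K4me3 and H3K36me3 were the most widely shared, although the H3K36me3 lists reached lower −log10 q values. Called in all 3 stages were 83.1% (Wilson 95% interval 82.2 to 83.9) of 7682 H3K4me3 regions and 82.2% (81.0 to 83.2) of 4807 H3K36me3 regions. For H3K27ac this share was 64.5% (63.5 to 65.4) of 9573 regions, and 18.9% (18.1 to 19.7) were called in a single stage, against 5.66% (5.17 to 6.20) of H3K4me3 regions. H3K27ac regions called in 1 stage were split between filopodial (641), aggregative (640) and cystic cells (528). H3K4me1 differed in another way: 60.3% (59.4 to 61.3) of 10967 regions were called in all 3 stages, and 2808 regions, 25.6%, were called in filopodial and aggregative but not in cystic cells. That share was 16.2% with equal numbers of top-ranked peaks in each stage, where regions called in cystic cells alone went from 721 to 1468, and it was 3872 of 9668 regions at a −log10 q of at least 10. The covered bases of filopodial and aggregative H3K4me1 had a Jaccard index of 0.787, while those of filopodial and cystic cells had 0.476. For H3K27ac the corresponding indices were 0.715 and 0.601. Regions called in 1 stage were narrow, with median widths of 254 to 292 bp for H3K27ac against 733 bp for regions called in all 3 stages, and the absence of a call does not show that the mark was absent. With peaks of −log10 q of at least 10, the share of H3K36me3 regions called in all 3 stages was 15.9%, the lowest of the marks.

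**Figure D1:**
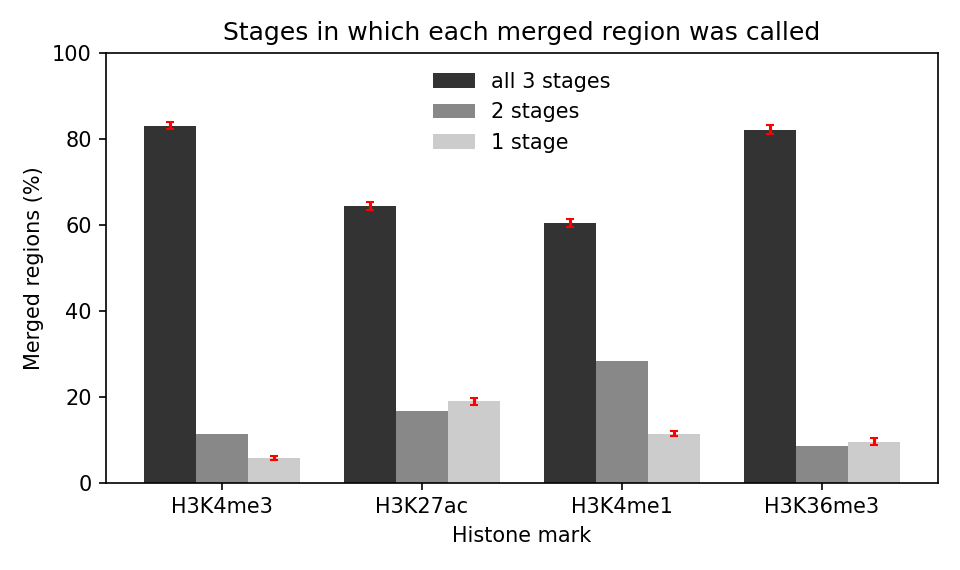
Percent of merged regions (vertical axis) called in 3, 2 or 1 of the stages for each histone mark (horizontal axis), with 1 library per mark and stage; red bars on the shares for 3 stages and for 1 stage are Wilson 95% intervals and cover counting error only. H3K4me3 and H3K36me3 stand above 80%, and with all deposited peaks 18.9% of H3K27ac regions were called in 1 stage; with equal numbers of peaks H3K4me1 was higher (21.5% against 19.6%), and at a −log10 q of at least 10 H3K36me3 was (46.6% against 21.1%).

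Marks were then compared with each other within a stage. H3K4me3 and H3K27ac lay on the same DNA: 65.6%, 61.3% and 58.6% of H3K4me3 bases in filopodial, aggregative and cystic cells were also covered by H3K27ac, 3.60, 3.27 and 3.69 times the mean of random placements. H3K36me3 lay elsewhere, covering 4.14%, 3.45% and 2.26% of H3K4me3 bases and 1.58%, 0.73% and 2.04% of H3K27ac bases, where random placement gave about 40.7%, 38.7% and 38.2%. H3K4me1 overlapped H3K27ac 1.36, 1.32 and 1.16 times as often as random placements. H3K4me1 covered 14.8% of H3K4me3 bases in filopodial cells (ratio 0.785) and 19.6% in aggregative cells (ratio 0.972, adjusted p = 0.0699 by permutation), but 2.97% in cystic cells (ratio 0.205). With equal numbers of top-ranked peaks in each stage the latter ratios were 0.808, 0.992 and 0.205. Apart from H3K4me1 on H3K4me3 in aggregative cells, the 18 pairs of mark and stage had an adjusted permutation p of 0.0021, from a raw p of 0.002, the smallest the placements can give.

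Accessible chromatin was described by 11927 nucleosome-free sites with a median width of 74 bp, which covered 3.82% of the span. Filopodial cells had 9226 of these sites, aggregative cells 9615 and cystic cells 3231. The largest class, 4738 sites (39.7%, Wilson 95% interval 38.9 to 40.6), was accessible in filopodial and aggregative cells only, and 2557 sites (21.4%, 20.7 to 22.2) in all 3 stages. Another 1870 sites were called in filopodial cells alone, 2088 in aggregative cells alone and 381 in cystic cells alone. Sites called in all 3 stages had a median width of 110 bp, and sites of a single stage 51 to 54 bp. Cystic cells had 1 ATAC library and a looser threshold of q = 0.01, so the number of cystic sites cannot be compared directly with the others.

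Over the merged list of sites, H3K4me3 and H3K27ac peaks overlapped accessible sites more often than random placements did, and H3K36me3 regions less often. Marks of every stage were set against this one list, of which 3231 sites were called in cystic cells. H3K4me3 overlapped 71.8%, 69.8% and 64.5% of the 11867 sites on the sequences tested in filopodial, aggregative and cystic cells, 3.07, 3.03 and 3.15 times the random mean. H3K27ac overlapped 56.0%, 52.7% and 41.7% of sites, 2.70, 2.46 and 2.29 times the random mean. H3K36me3 overlapped 2.54%, 2.26% and 1.68% of sites, where random placement gave 41.7%, 39.8% and 39.4%. Each of these had an adjusted permutation p of 0.0024. H3K4me1 overlapped 18.8% of sites in filopodial cells, less often than at random (ratio 0.861, adjusted permutation p = 0.0024), and 22.4% and 16.5% in aggregative and cystic cells, where the ratios of 0.963 and 0.986 had adjusted p of 0.0893 and 0.593 by permutation. These calls moved with the setting: where 50% of the site had to be covered the ratios were 0.862 (adjusted permutation p = 0.0022) and 0.918 (0.006), and at a −log10 q of at least 10 the cystic ratio was 1.18 (0.0044), in the opposite direction. Within 500 bp, H3K4me1 lay near 72.5%, 76.3% and 58.5% of sites, 1.41, 1.45 and 1.46 times the random mean, an alternative that turned its direction. Around the sites of a stage, averaged over both sides, H3K4me1 coverage was lowest at the midpoint, at 13.2%, 16.3% and 11.9%, and reached 37.8% and 40.2% at 700 bp in filopodial and aggregative cells and 28.3% at 850 bp in cystic cells. H3K36me3 rose from 1.99% at the midpoint of filopodial sites to 53.3% at 2050 bp. Cystic H3K27ac covered 17.9% of cystic sites at the midpoint, close to its 15.6% of the span, and 27.6% at 400 bp. In filopodial (52.6%) and aggregative cells (44.7%) H3K27ac was highest at the midpoint. The sets of sites were unlike, since 2557 of the 3231 cystic sites were accessible in all 3 stages. At those sites H3K27ac overlapped 40.67%, 37.15% and 25.89% in filopodial, aggregative and cystic cells. At sites accessible in filopodial and aggregative cells only, cystic H3K27ac overlapped 46.92%.

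**Figure D2:**
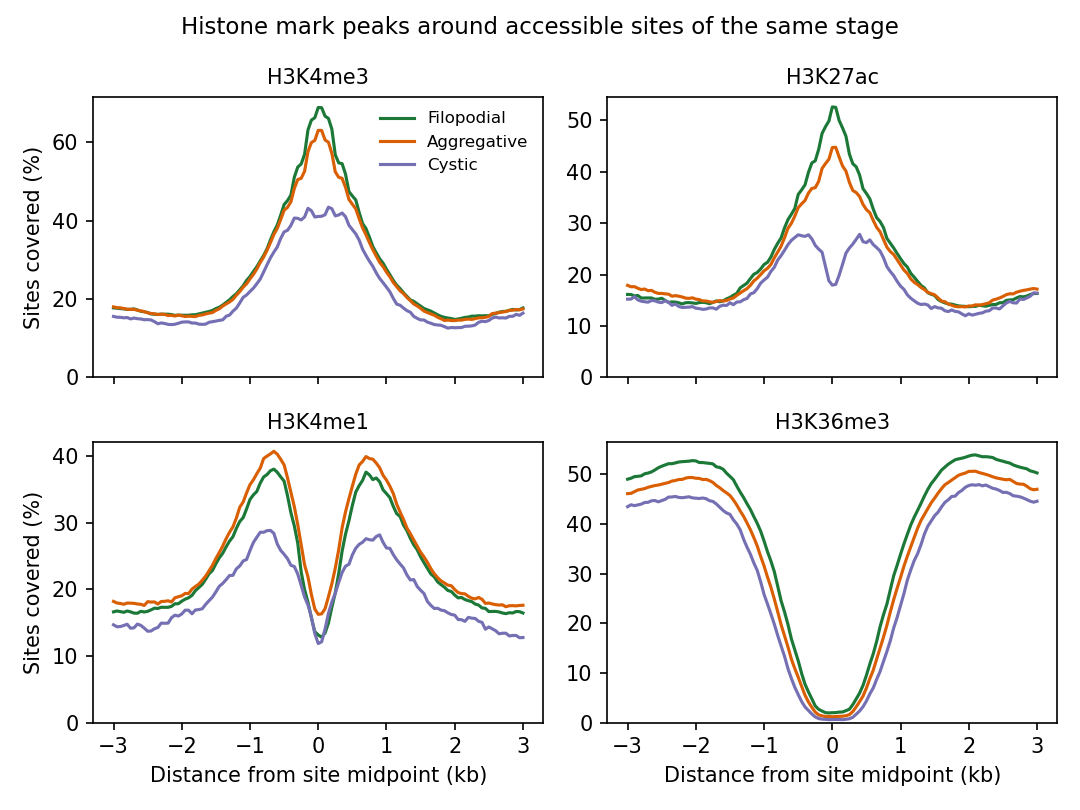
Percent of accessible sites of a stage (vertical axis) whose position at a given distance from the site midpoint in kb (horizontal axis) was covered by a peak of the mark in the same stage; lines stand for the 3 stages, which have different sets of sites, and vertical scales differ between panels. H3K4me3 and H3K27ac peak within 50 bp of the midpoint in filopodial and aggregative cells, H3K4me1 peaks on both sides at 650 to 900 bp, and H3K36me3 is lowest at the sites.

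Whether a site accessible in 1 stage carried a mark of that stage was asked last. Of 1931 sites accessible in filopodial but not aggregative cells, 106 had H3K27ac within 500 bp in filopodial cells alone and 35 in aggregative cells alone. Among sites with the peak in only 1 of these stages, the filopodial peak thus made up 75.2% (67.4 to 81.6). Of 2320 sites accessible in aggregative but not filopodial cells the numbers were 99 and 79, and the share 55.6% (48.3 to 62.7). Most sites of both kinds had no such difference in H3K27ac. These intervals treat sites as independent, although neighbouring sites can share a peak. The net gain of filopodial H3K27ac differed by 2.81 percentage points between both kinds of site (adjusted p = 0.004 by label rotation), and by 0.92 points (adjusted p = 0.372) when the peak had to overlap the site itself. For H3K4me3 the difference was −0.24 points (adjusted p = 0.731 by label rotation), and −1.41 points, past the threshold (adjusted p = 0.042), when the peak had to overlap the site. For H3K4me1 it was −0.30 points (adjusted p = 0.739) and at a −log10 q of at least 10 it was −2.27, past the threshold (adjusted p = 0.0405). For H3K36me3 it was 0.46 (adjusted p = 0.731), but 0.66 (adjusted p = 0.0034) with overlap of the site and −1.91, in the opposite direction (adjusted p = 0.032), at the stricter q. Sites that differed between filopodial and cystic cells gave larger differences: 11.2 points for H3K4me3, 10.95 for H3K27ac and 10.6 for H3K4me1, each with an adjusted p of 0.0024, but 1.05 for H3K36me3 (adjusted p = 0.731). At sites accessible in cystic but not filopodial cells, the mark was called in filopodial cells alone and in cystic cells alone at 51 and 78 sites for H3K4me3. These counts were 72 and 69 for H3K27ac, and 89 and 48 for H3K4me1. With all deposited peaks, the cystic peak was thus the more frequent one for H3K4me3 only. With equal numbers of top-ranked peaks it was the more frequent one for all 3 marks, at 44 and 90, 65 and 74, and 67 and 77 sites. Where the peak had to overlap the site, the counts for H3K4me3 were 58 and 58. Between aggregative and cystic cells the differences were 16.9 points for H3K4me3 and 8.62 for H3K27ac, each with an adjusted p of 0.0024, 5.64 for H3K4me1 (adjusted p = 0.0291) and −1.64 for H3K36me3 (adjusted p = 0.563). At sites accessible in cystic but not aggregative cells, aggregative and cystic peaks alone numbered 25 and 73 for H3K4me3, 43 and 37 for H3K27ac, and 82 and 30 for H3K4me1. With equal numbers of top-ranked peaks these were 22 and 78, 35 and 53, and 62 and 50, so the order turned for H3K27ac. The H3K4me1 differences turned to −6.54 and −11.5 points when the peak had to overlap the site, and the latter comparison missed the threshold at the stricter q (5.24 points, adjusted p = 0.0732) and with equal numbers of peaks (3.63 points, adjusted p = 0.231).

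Single sites of this kind were chosen among sites of 1 stage with H3K27ac within 500 bp in that stage alone, by peak fold. The filopodial one lay on supercontig 2.4 at 1391197 to 1391245 (fold 2.81). The aggregative one lay on supercontig 2.14 at 761993 to 762076 (fold 3.15), and the cystic one on supercontig 2.8 at 1465856 to 1465909 (fold 2.34). The H3K27ac peaks lay beside these sites without overlapping them, at 1389871 to 1390887, 762514 to 763688 and 1466008 to 1466346. The filopodial site also had H3K4me3 nearby in filopodial and aggregative cells and H3K4me1 in all 3 stages. The aggregative and the cystic site had no H3K4me3 peak within that distance in any stage, and both had H3K4me1 in all 3. The genome build was not given in the sources used here, and the genes at these positions were not analysed here.

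The RNA-seq comparison asked how inhibition of histone deacetylases changed expression in filopodial cells. The most abundant transcript of the control, CAOG_06989T0, made up 20.8% and 20.4% of TPM in the DMSO libraries and 3.57% and 3.50% in the TSA libraries. It fell from 205810 ± 3059 to 35343 ± 500 TPM (SD, n = 2 each; log2 change −2.54, SE 0.06, limma adjusted p = 1.95e-10); it was chosen after its values were seen. The 2 transcripts with the largest rise were CAOG_03409T0 and CAOG_05434T0: CAOG_03409T0 went from 75.2 ± 0.0547 to 42021 ± 107 TPM (log2 change 9.11, SE 0.05) and CAOG_05434T0 from 110 ± 2.58 to 58728 ± 48.8 TPM (log2 change 9.05, SE 0.05), both with a limma adjusted p of 5.49e-15. Together they held 10.1% of TPM under TSA and 0.0185% in DMSO. The steepest falls were those of CAOG_03522T2, from 287 ± 61.5 to 7.19 ± 0.0541 TPM (log2 change −5.12, SE 0.12, limma adjusted p = 1.63e-10), and CAOG_07313T0, from 405 ± 0.636 to 18.8 ± 2.70 TPM (log2 change −4.37, SE 0.09, limma adjusted p = 6.9e-11).

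Expression was spread over more transcripts under TSA. The median transcript had 11.9 and 13.3 TPM in the DMSO libraries and 24.2 and 24.0 TPM in the TSA libraries. Transcripts listed at 0 numbered 257 and 229 in DMSO and 99 and 89 under TSA. That count also depends on read depth, which TPM do not hold, so the effect of depth on it could not be measured. In DMSO 50% of TPM was held by 56 and 59 transcripts, and under TSA by 120 and 122. Without CAOG_06989T0 these numbers were 100 and 106 in DMSO and 136 and 138 under TSA, so the difference was smaller. With TPM as deposited, 330 transcripts were under 1 TPM in both DMSO libraries and at 5 TPM or more in both TSA libraries, while 4 went the other way; after trimmed-mean rescaling the counts were 256 and 9.

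Of 8302 tested transcripts, 7162 changed by limma, 5760 higher and 1402 lower under TSA, with a median log2 change of 0.71. Changes of at least 2-fold were seen in 3172 higher and 314 lower transcripts. The split depended on the scale. After rescaling each library by a trimmed mean, 6842 transcripts changed, 3689 higher and 3153 lower, and the median was 0.09; after quantile normalization 3017 were higher and 3887 lower, and the median was −0.13. The share of calls that were higher was thus 80.4% as deposited, 53.9% after rescaling and 43.7% after quantile normalization. All 3689 transcripts called higher after rescaling were called higher as deposited, and the 1402 called lower as deposited were called lower after rescaling, while 649 changed from higher to lower and 1422 from higher to uncalled. At least 2-fold changes after rescaling numbered 1671 higher and 1113 lower. On that scale CAOG_03409T0 rose by 8.44, CAOG_05434T0 by 8.38 and CAOG_06989T0 fell by 3.22 on the log2 scale. TPM give shares of the transcriptome, so these values hold no change of total RNA.

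**Figure D3:**
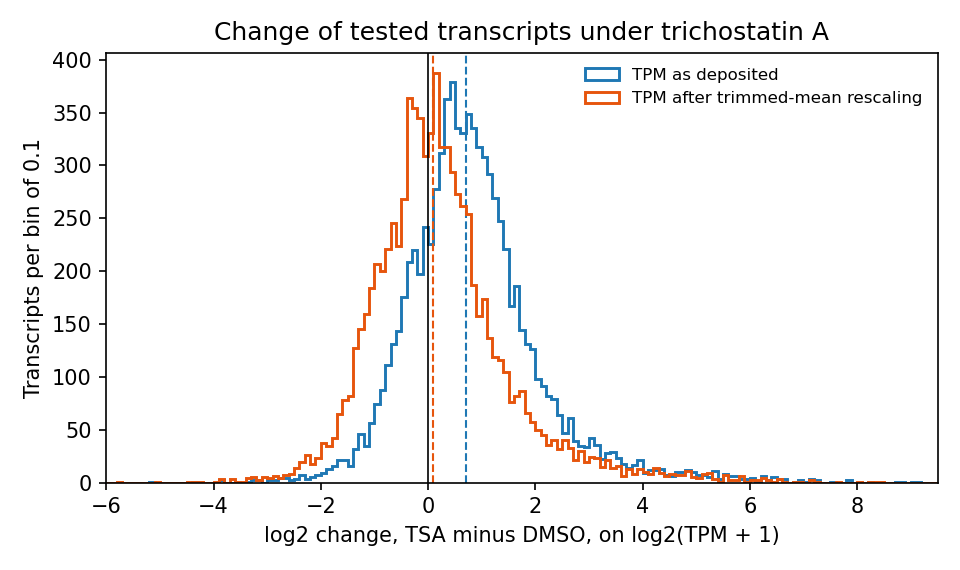
Number of tested transcripts per bin of 0.1 (vertical axis) by log2 change under TSA on the log2(TPM + 1) scale (horizontal axis), for TPM as deposited and after trimmed-mean rescaling; dashed lines mark the medians, 0.71 and 0.09. The right tail of raised transcripts is longer than the left tail on both scales.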

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

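Settings added after the data had been seen were the crossed pairing, the removal of the most abundant transcript, the block and left-out libraries after rescaling, both limits on peaks in the overlap between marks, the 500 bp distance for sites carrying a mark, and every setting of the test on stage-specific sites. Of 314 values under an alternative setting, 279 were counted as unchanged and 35 were not. A value counted as unchanged if it kept its direction and side of the threshold, or its size. It also did so if its direction turned while neither value passed the threshold. That was so for H3K4me3 at sites differing between filopodial and aggregative cells, with −0.24 points as reported and 0.48 with equal numbers of peaks. The changes of CAOG_03409T0, CAOG_05434T0, CAOG_03522T2, CAOG_07313T0 and CAOG_06989T0 kept their direction in all 69 values from alternative settings. With trimmed-mean rescaling 3689 transcripts were higher and 3153 lower, and with quantile normalization 3017 and 3887, which follows from setting the centre of each library equal. The median log2 change was 0.087 and −0.126 in these fits, 0.53 with a pseudocount of 5 and 0.46 without the most abundant transcript. Leaving out 1 library gave a median log2 change of 0.639 to 0.771. In these fits 1 group held a single library, so the spread came from the other group alone. With the replicate block 7072 transcripts changed, and with a crossed pairing 7285. The labels do not say whether the numbers pair the samples. Deviations from the group means correlated at −0.135 between libraries with the same number. With 2 libraries per group the crossed value, 0.135, must be the same number with its sign turned, so it adds no information. At a −log10 q of at least 10, H3K36me3 kept 827 filopodial, 1478 aggregative and 613 cystic regions, and cystic H3K4me1 5031 intervals, because weaker peaks were removed; regions called in all 3 stages were then 82.2% for H3K4me3, 58.6% for H3K27ac, 43.2% for H3K4me1 and 15.9% for H3K36me3. With an overlap of at least 50% of the shorter region the shares were 63.5% for H3K27ac and 59.4% for H3K4me1, and with equal numbers of top-ranked peaks 54.2% for H3K4me1. Shuffled peaks gave a ratio of 0.972 for H3K4me1 on aggregative H3K4me3, now past the threshold. For sites carrying H3K4me1 the ratios to random were 1.41, 1.45 and 1.46 within 500 bp, 0.862 in aggregative and 0.918 in cystic cells where 50% of the site had to be covered, and 1.18 in cystic cells at the stricter q, all past the threshold. In the test on stage-specific sites, overlap with the site itself gave filopodial against aggregative differences of −1.41 points for H3K4me3 and 0.66 for H3K36me3, both now past the threshold, and 0.92 for H3K27ac, no longer past it, and H3K4me1 differences of −6.54 (filopodial against cystic) and −11.5 (aggregative against cystic). The stricter q gave −2.27 for H3K4me1 and −1.91, a turned direction, for H3K36me3 between filopodial and aggregative cells, both past the threshold. For H3K4me1 between aggregative and cystic cells, 5.64 as reported became 5.24 at the stricter q and 3.63 with equal numbers of peaks, and these 2 missed the threshold. The cause of these changes was not tested. Gene lists and every planned result that needs gene positions were not run. Read depth was not given, so the effect of depth on the number of peaks could not be measured.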

Other observations

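Tests chosen only after the result was seen were the share of sites overlapped by H3K27ac among sites near H3K4me3, the median change without the most abundant transcript, and the grouping of transcripts by the mean of 4 libraries. H3K36me3 regions were bordered by promoter marks. In filopodial, aggregative and cystic cells, 69.6%, 64.6% and 56.6% of these regions had H3K4me3 within 1000 bp of both ends, against 19.3%, 19.0% and 16.3% in 100 random placements. H3K4me1 lay at both ends of 66.4%, 68.0% and 33.7% of H3K36me3 regions, against 27.9%, 29.0% and 17.4% at random. Most filopodial sites had H3K4me3 and H3K27ac together within 500 bp (77.9%, Wilson 95% interval 77.0 to 78.8), and 3.35% (3.00 to 3.74) had H3K4me1 and H3K27ac without H3K4me3. In cystic cells these shares were 56.0% (54.3 to 57.7) and 5.82% (5.06 to 6.68), over a smaller set of sites. Random placements were not run for these combinations. For single marks, random placements of the merged sites had filopodial H3K4me3 within 500 bp at 44.4% and H3K27ac at 43.5%. A window of that width thus often holds H3K4me3 at random, which limits what the shares without it can show.

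Accessible sites were clustered. Of all sites, 50.4% had the next site within 500 bp, against 19.7% for random positions. The densest window of 10000 bp, on supercontig 2.2 from 1890001 to 1900000, held 19 sites. Of these, 16 were accessible in filopodial, 16 in aggregative and 5 in cystic cells. In filopodial cells H3K27ac covered 6.2% of it, H3K4me3 21.9%, H3K4me1 34.7% and H3K36me3 32.6%. The low H3K27ac share was particular to it, since the next densest windows had 38.3%, 43.8%, 26.4% and 29.2% in filopodial cells. The window at the start of supercontig 2.13 (1 to 10000) held 17 sites, 15 of them aggregative and 7 filopodial. The median window held 4 sites. A pair of sites accessible in cystic cells alone, on supercontig 2.8 at 1465856 to 1465909 and at 1466353 to 1466408, stood on either side of a single H3K27ac peak called in cystic cells alone.

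H3K27ac overlapped fewer of the sites accessible in all 3 stages than of those accessible in filopodial and aggregative cells only, 40.7% against 64.7% in filopodial cells. A nucleosome-free gap wide enough to split the peak was argued against as the whole cause, since the share within 500 bp was still lower by −5.97 points (77.0% against 83.0%), although most of the difference was gone at that distance. Fewer H3K4me3 domains near the widely accessible sites are a candidate explanation of part of that remainder, but not of all of it. Among sites with H3K4me3 within 500 bp the difference was still −3.14 points. The shares there were 84.28% (Wilson interval 82.69 to 85.75) against 87.42% (86.4 to 88.37), with intervals that did not overlap. Fewer such domains within 500 bp were argued against as the whole cause of the difference at the site itself. That difference was −23.6 points among the same sites (45.7% against 69.3%). Over all sites of both classes, filopodial H3K4me3 also overlapped fewer of those accessible in all 3 stages, 62.9% against 79.5%. Its overlap with the site was not held equal, so its position relative to the site was not tested. What sets the difference at the site stays open, a gap included as part of it, and no biological explanation was tested.

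Most transcripts were higher under TSA as deposited, which loss of the most abundant transcript alone did not account for (median log2 change of 0.46 without it), and the transcripts lowest in DMSO rose most. Grouped by 1 DMSO library with the change taken against the other, the lowest of 4 equal groups of transcripts exceeded the highest by 1.36 on the log2 scale. This argued against noise of a single library in the grouping level as the cause. Deviations shared by both DMSO libraries would remain in that split. The filter on the mean of 4 libraries also keeps transcripts near 0 in DMSO only where they are higher under TSA, and its effect was not measured. Grouped by a TSA library, which carries the opposite bias, the difference was −0.066, and grouped by the mean of 4 libraries, which takes neither side, it was 0.744, so the choice of the DMSO side is a candidate explanation for part of the difference but not for all of it. The value of 0.744 also argued against the closed sum of TPM, since 1 factor above 1 raises low transcripts no more than abundant ones on this scale, while rescaling by 1 factor per library could not have removed the difference and decided nothing. What narrowed the log2 levels under TSA (SD over transcripts 1.84 and 1.85, against 2.20 and 2.15 in DMSO) stays open.

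Neighbouring genes changed alike under TSA, to a small degree: across 7021 adjacent pairs the rescaled changes had a Spearman rho of 0.0904, above the highest of 1000 permutations, 0.0477 (adjusted p = 0.0012). Genes are not independent replicates, and each change is a difference between the means of 2 and 2 libraries. Reads shared by adjacent models were argued against as the whole cause, since genes 2 to 5 places apart had a mean rho of 0.0638, above the permuted maximum of 0.0193. A similar mean level of neighbours over the 4 libraries was also argued against, because with the trend on that level removed the adjacent rho was 0.146. That mean includes the TSA libraries, so a similar level of neighbours in DMSO alone was not tested. Reads shared among tandem gene copies were not tested and stay open, and no biological explanation was tested.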
